A study of Mus musculus with 8 samples.

How the data were processed

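The series holds bulk RNA sequencing of the right ventricle of 8-week-old female mice that were wild type (WT) or lacked Fpr2 (Fpr2-KO), the gene of formyl peptide receptor 2. Control mice were kept at normal oxygen for 21 days. SuHx mice received Sugen, an inhibitor of VEGF receptors, at 20 mg/kg and were kept in hypoxia for 3 weeks, a standard way to raise pulmonary artery pressure and load the right ventricle in rodents. Each of the 4 combinations of genotype and treatment has 2 libraries, 8 in all. Per the labels' protocols, RNA with an integrity number above 7.0 was selected for poly(A), fragmented, made into libraries in which dUTP marks the second strand, and sequenced in pairs on a NovaSeq instrument.

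The deposited table gives counts per gene, with Ensembl identifiers, symbols, positions, and GO and KEGG annotations, and per the submitters' processing notes the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR with the mm10 build. The roles and order of these tools, the strand setting and the annotation release are not given in the sources used here. The counts are whole numbers, were taken as deposited and carry no normalization. Genes that overlap on opposite strands or share exons are therefore uncertain. The same table holds 8 columns of FPKM values that the authors made from the same libraries, and these deposited FPKM values were not used. The table has 30495 genes, of which 1289 are at 0 in every library. Of the identifiers, 99.7% are in GENCODE release M21, which uses the same assembly, and 99.99% of those overlap its position for the gene. Positions below are those of the deposited table.

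Samples were grouped by their titles. Another label field of 3 of the Fpr2-KO samples names Fpr3, Fpr4 and Fpr5 in place of Fpr2, and the titles were followed. The titles number the samples of each group 1 and 2, and the column names of the table do so for WT control alone. The other 6 columns are numbered 1 and 3 or 2 and 3, so these columns were used as replicates of their group and no column was paired with another in the tests. Libraries are called by the number in their column name (1 and 2 for WT control, 1 and 3 for WT SuHx, 2 and 3 for Fpr2-KO control, 2 and 3 for Fpr2-KO SuHx). The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The libraries of a pair were not copies of one another: the chi-square per degree of freedom of their counts was 24.4 to 80.7, far above sampling noise, and log2 CPM correlated at 0.966 to 0.975.

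Total counts per library were 67965311 to 76292772, and mitochondrially coded genes took 24.2% to 28.2% of them. At this depth 1 count is far below 1 CPM, and precision is set by the number of libraries. For a gene at 0, the limit that 3 counts allow is used as a floor. A fold against a group at 0 is then given as a lower bound, computed from the summed counts of both groups, and such floors cover counting error only because reads carried no molecular identifiers.

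Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 19083 tested genes and removed 11412. Library sizes were scaled by TMM. The common biological coefficient of variation was 25.1%. All 8 libraries entered 1 quasi-likelihood fit (glmQLFit, robust) with a mean for each of the 4 groups, which leaves 4 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the tested genes, and a gene is called when the adjusted p is under 0.05. There were 7 comparisons: SuHx against control in WT, the same in Fpr2-KO, Fpr2-KO against WT in control mice, the same in SuHx mice, the genotype by SuHx interaction, and both main effects averaged over the other factor. Log2 fold changes are given with the standard error implied by the F statistic, and levels are CPM, counts scaled to the library size, as mean ± SD of n = 2 libraries.

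Before the data were examined, 38 gene lists, the rule for named genes and the alternatives were fixed. The lists cover cardiac muscle, matrix, cell types, oxygen and fuel use, growth, interferon, antigen presentation, inflammation, Fpr2-related mediators, stress and handling. Each list with at least 3 tested members was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes. It was tested again with an estimated correlation and with fry, which asks whether a list moves one way without comparing it with other genes. With an estimated correlation camera takes its p from the 4 residual degrees of freedom, so few lists could pass. A failure there is therefore no evidence against a list. GO and KEGG terms with 15 to 300 tested genes were tested with camera. Genes are named if they were among the 8 largest changes in either direction that were called, did not overlap between libraries of the groups and had a mean of at least 5 CPM. The 4 list members with the smallest p in a comparison are named too, as are Fpr2, Fpr1, Anxa1, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Postn and the sex-check genes. Genes called by a number alone were not named, and the 3 genes with the smallest p stand in where a comparison had no call. Genes named from the second atrial list, of the aryl hydrocarbon receptor list and of the substrain list were chosen after the main results had been seen.

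The procedure was tested on simulated counts for the 19083 genes. The 200 changed genes were drawn from those with a mean above 1 CPM, so recovery of rarer genes was not tested. SuHx against control in WT recovered 42.5% of 2-fold and 89.5% of 4-fold changes, with 5.56% and 9.6% of the calls false. The interaction recovered 7% and 77.5%, with 6.67% and 4.91% false. SuHx averaged over genotypes recovered 77% and 95%, with 11% and 7.32% false. Comparisons of Fpr2-KO with WT were not simulated. The alternatives were RLE normalization, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, the 4 libraries of a comparison alone, leaving out each library, the column number as a replicate block (added later), counts without mitochondrial and haemoglobin genes, and other thresholds. Y-linked genes of the sex-check list were not analysed here. Some results for single genes are not reported here.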

Results

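Right ventricles of female WT and Fpr2-KO mice were profiled by RNA sequencing under control conditions and after SuHx exposure. Fpr2 encodes a G protein-coupled receptor of leukocytes and other cells that binds formylated peptides, annexin A1 and lipid mediators. The series concerns the part of this receptor in sex differences of right ventricular dysfunction in pulmonary hypertension. The 8 libraries fall into 4 groups of 2 and hold 67965311 to 76292772 counts each.

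Fpr2 (ENSMUSG00000052270, mm10 chromosome 17, 17887824 to 17893952, plus strand) was counted 19 and 23 times in the WT control libraries and 12 and 12 times in the WT SuHx libraries. All 4 Fpr2-KO libraries held 0 counts of it. The 66 counts in the 4 WT libraries against 0 in Fpr2-KO put the gene at least 21.5-fold lower in Fpr2-KO, with a floor of 3 counts over the 4 libraries. The libraries thus follow the genotype in their column names and titles, although another label field of 3 of the Fpr2-KO samples names Fpr3, Fpr4 and Fpr5 in place of Fpr2. Fpr2 itself was a rare transcript here, at 0.231 CPM over the WT libraries. Its paralog Fpr1 had 0 to 39 counts per library, too few for a comparison. Xist, the X-inactivation transcript of female cells, lay between 198 and 366 CPM of the library total in all 8 libraries.

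Libraries separated first by treatment. The first principal component took 37.2% of the variance, with the 4 SuHx libraries between 49.2 and 55.5. The Fpr2-KO controls lay at -28.9 and -39.3 and the WT controls at -60.3 and -84.1. On the second component WT control library 1, at 65.5, lay opposite the Fpr2-KO controls, at -47.2 and -61.7, and Fpr2-KO SuHx library 2 was set apart on the third, at -69.9.

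**Figure D1:**
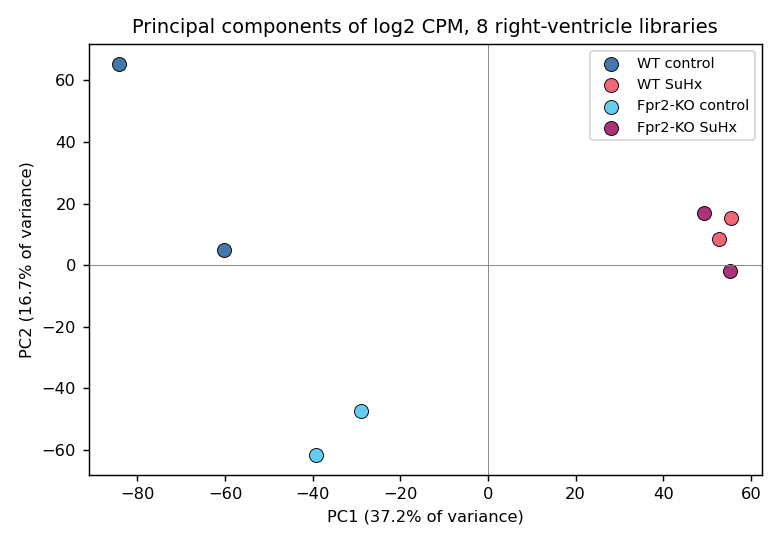
Scores of the 8 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by group. The SuHx libraries of both genotypes lie between 49.2 and 55.5 on the first component, and the Fpr2-KO controls, at -28.9 and -39.3, lie nearer to them than the WT controls.

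The first comparison asks how the WT right ventricle responds to SuHx. Most genes of the fatty acid oxidation list were called lower and most glycolytic genes higher. Of 34 fatty acid oxidation genes, 28 were called lower and 0 higher (30 lower adjusted over the list alone; camera adjusted p = 6.46e-19, adjusted p = 0.306 with an estimated correlation). Pdk4, the gene of a kinase that inhibits the pyruvate dehydrogenase complex, fell from 3608 ± 1500 to 191 ± 102 CPM (log2 fold change -4.24 ± 0.53, edgeR adjusted p = 0.00517). The acyl-CoA thioesterases Acot1 and Acot2 changed by -4.38 ± 0.47 and -2.27 ± 0.18, the fatty acid transporter Slc27a1 by -1.79 ± 0.16 and Cpt1a, which carries fatty acids toward oxidation, by -1.46 ± 0.18. Of 18 glycolytic genes, 11 were called higher and 0 lower (13 and 1 adjusted over the list alone; camera adjusted p = 4.68e-06, adjusted p = 0.306 with an estimated correlation). They include Pgam2 (0.95 ± 0.09), Pfkl (0.98 ± 0.11) and Eno3 (0.87 ± 0.11). Nuclear genes of oxidative phosphorylation did not pass the list test, with 2 of 34 called higher. Mitochondrially coded genes had 3 of 13 called higher (camera adjusted p = 0.000971, adjusted p = 0.575 with an estimated correlation), such as mt-Nd2 at 0.48 ± 0.10.

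Muscle genes changed in both directions in WT. Skeletal alpha-actin, encoded by Acta1 and expressed in loaded or fetal myocardium, rose from 27.6 ± 2.42 to 210 ± 92.3 CPM (log2 fold change 2.93 ± 0.31, edgeR adjusted p = 0.00161). Myh7, the slow beta-myosin heavy chain that is usually raised with hypertrophy in mice, was lower, at 4692 ± 2490 CPM in controls and 555 ± 17.2 CPM in SuHx (log2 fold change -3.08 ± 0.61, edgeR adjusted p = 0.0232). The natriuretic peptide genes Nppa (-1.02 ± 1.66) and Nppb (-0.50 ± 0.67) and the fast myosin gene Myh6 (0.53 ± 0.20) were not called. The hypertrophy list had 3 genes higher and 4 lower of 15 and was not called (camera adjusted p = 0.438). Xirp2 (0.87 ± 0.13) was among the higher and Xirp1 (-1.88 ± 0.10) and Rcan1 (-1.05 ± 0.20) among the lower. Of 24 adult contractile genes, 7 were called higher and 0 lower (13 and 1 adjusted over the list alone; camera adjusted p = 0.000527, adjusted p = 0.383 with an estimated correlation), among them Actc1 (1.56 ± 0.20), Mybpc3 (1.43 ± 0.15) and Casq2 (1.33 ± 0.12).

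Lists of matrix, vessel and proliferation genes had more genes called higher than lower in WT. Of 36 extracellular matrix genes, 21 were called higher and 3 lower (22 and 3 adjusted over the list alone; camera adjusted p = 4.68e-06, adjusted p = 0.306 with an estimated correlation). Periostin, a matrix protein of activated fibroblasts encoded by Postn, rose from 15.9 ± 4.51 to 70.7 ± 0.56 CPM (log2 fold change 2.15 ± 0.21, edgeR adjusted p = 0.000829). Col1a1 rose by 1.79 ± 0.37 and Sparc by 1.42 ± 0.16, whereas Lox, a collagen crosslinking enzyme, fell by 2.57 and the matricellular gene Ccn2 by 3.48. Apln and its receptor gene Aplnr, which act in new vessels, rose by 4.65 ± 0.32 and 4.25 ± 0.41. The VEGF and angiogenesis list had 10 of 18 genes higher and 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 0.000121, adjusted p = 0.306 with an estimated correlation), such as Nrp1 (1.01 ± 0.11) and Angpt2 (1.43 ± 0.21). Endothelial markers had 8 of 20 higher and 1 lower (11 and 2 adjusted over the list alone; Tie1 0.96 ± 0.10, Kdr 1.08 ± 0.14; camera adjusted p = 0.00088) and mural cell markers 7 of 12 higher and 0 lower (7 and 0 adjusted over the list alone; Acta2 1.88 ± 0.21; camera adjusted p = 0.00088). With an estimated correlation these had adjusted p = 0.312 and adjusted p = 0.306. Of 30 cell cycle genes, 20 were called higher and 1 lower (22 and 1 adjusted over the list alone; camera adjusted p = 4.89e-08, adjusted p = 0.306 with an estimated correlation), among them Mcm5 (2.86 ± 0.29), Cenpf (2.83 ± 0.30) and Tpx2 (3.67 ± 0.48).

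So did lists of interferon-stimulated and antigen presentation genes. All but 2 of the 25 interferon genes, 23, were called higher and 0 lower (23 adjusted over the list alone; camera adjusted p = 1.64e-12, adjusted p = 0.306 with an estimated correlation). Examples are Ifi44 (2.47 ± 0.28), Oasl2 (2.22 ± 0.25) and Xaf1 (1.69 ± 0.17). Of 20 antigen presentation genes, 14 were called higher and 0 lower (18 adjusted over the list alone; camera adjusted p = 2.08e-10, adjusted p = 0.306 with an estimated correlation). The chemokine gene Cxcl9 rose by 2.89 ± 0.28 and the guanylate-binding protein gene Gbp2 by 2.53 ± 0.18. Macrophage and monocyte markers had 12 of 20 higher and 0 lower (14 and 1 adjusted over the list alone; camera adjusted p = 9.67e-06, adjusted p = 0.321 with an estimated correlation), with Cx3cr1 at 4.26 ± 0.49 and Adgre1 at 1.85 ± 0.24. B cell markers had 4 of 11 higher (5 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.426 with an estimated correlation), from low levels: Cd79b went from 0.19 ± 0.05 to 1.21 ± 0.46 CPM. Cytokines and other inflammatory mediators were not called as a list, with 4 of 31 higher and 4 lower, among them Cxcl16 and Socs3 (-1.40 ± 0.23). Of the 14 tested genes of Fpr ligands and lipid mediators, Anxa2 alone was called (1.44 ± 0.14), and Anxa1, the gene of an Fpr2 ligand, was at 0.08 ± 0.17 and not called.

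Other lists had more genes called lower than higher in WT SuHx. Of 25 antioxidant genes, 11 were called lower and 2 higher (14 and 5 adjusted over the list alone), with catalase, Cat, at -1.52 ± 0.12 and Sod1 at -0.95 ± 0.12 (camera adjusted p = 0.00389, adjusted p = 0.426 with an estimated correlation). Heat shock genes had 4 of 14 lower and 0 higher (4 adjusted over the list alone; Hspb1 -1.19 ± 0.16; camera adjusted p = 0.00889, adjusted p = 0.646 with an estimated correlation). Ribosomal protein genes had 14 of 30 lower and 0 higher (25 adjusted over the list alone; Rps9 -0.69 ± 0.13; camera adjusted p = 1.98e-08, adjusted p = 0.507 with an estimated correlation). Lists of handling and state moved with these groups. Genes of glucocorticoid action and fasting had 6 of 15 lower and 0 higher (9 adjusted over the list alone; camera adjusted p = 6.67e-07, adjusted p = 0.306 with an estimated correlation), with Fkbp5 going from 125 ± 59.0 to 15.8 ± 10.6 CPM. Immediate early genes had 3 of 19 lower (3 adjusted over the list alone; camera adjusted p = 0.00088, adjusted p = 0.306 with an estimated correlation), with Nr4a1 at -4.50 ± 0.37. Adipocyte markers had 3 of 7 lower (5 adjusted over the list alone; camera adjusted p = 0.000681, adjusted p = 0.306 with an estimated correlation), with Lipe, which heart muscle also expresses, at -1.47 ± 0.15. Clock genes split, 5 of 17 higher and 5 lower, with Dbp at 1.75 ± 0.16 and Cry2 at -0.99 ± 0.18. Hypoxia targets split too, 7 of 23 higher and 4 lower, with Egln3 at 1.49 ± 0.24 and Bnip3 at -2.42 ± 0.20. Lists that were not called in WT include fibroblast markers (3 of 12 higher, 2 lower), genes of estrogen, apelin and BMP signalling (3 of 21 higher, 0 lower) and stress response genes of the ATF4 and unfolded protein pathways (3 of 24 higher, 3 lower). Markers of neutrophils had 1 of 10 lower, T and NK cells 1 of 13 higher and skeletal muscle 1 of 6 higher. Markers of red cells (7), atrial muscle (8), thymus (3), mesothelium (9) and Schwann cells (7) had 0 called. The airway and sex-check lists had 2 and 1 tested genes, too few for a list test. The most strongly raised gene named was Cyp1a1 (chromosome 9, 57687928 to 57703824), a xenobiotic-metabolizing cytochrome P450, which went from 1.70 ± 0.58 to 234 ± 30.8 CPM (log2 fold change 7.11 ± 0.38, edgeR adjusted p = 0.000399).

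In all, edgeR called 3919 of 19083 genes in WT SuHx against control, 2082 higher and 1837 lower, and 1608 of these changed at least 2-fold. The count was 1318 without WT SuHx library 1, 1450 without WT SuHx library 3, and 2214 without WT control library 1 and Fpr2-KO SuHx library 2 together, a pair chosen after the data were seen.

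**Figure D2:**
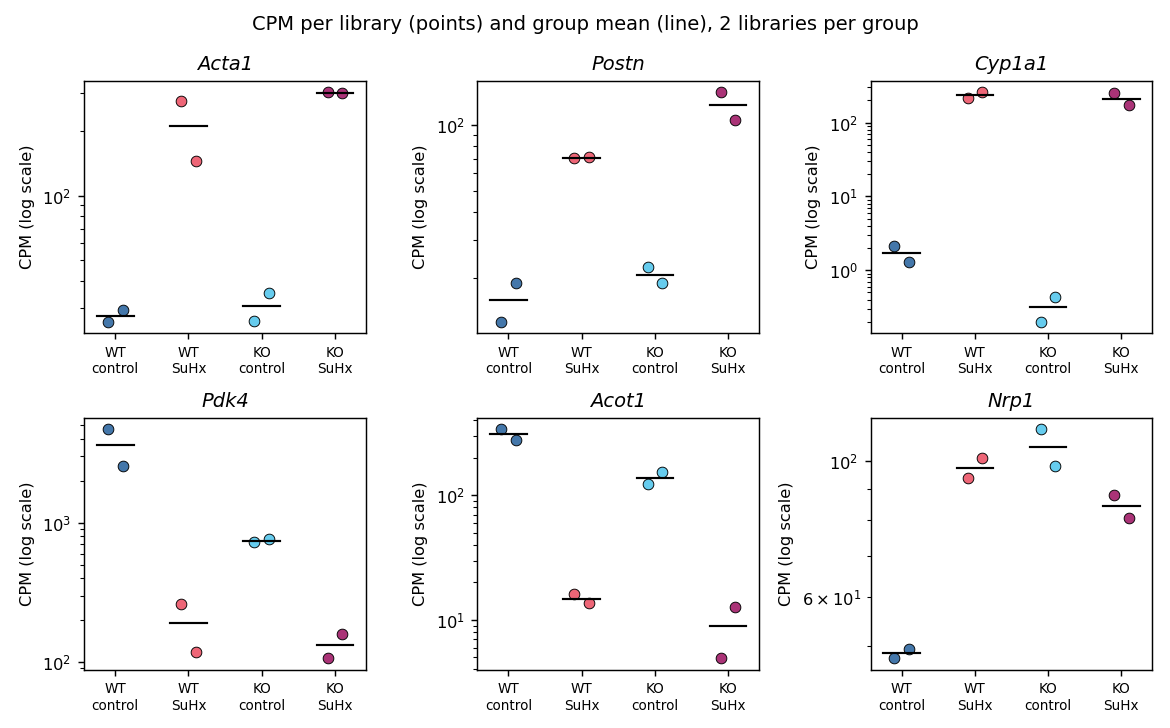
CPM of 6 genes (y axes, log scale) in each of the 8 libraries by group (x axes), with a line at the mean of the 2 libraries. Acta1, Postn and Cyp1a1 were higher in every SuHx library than in every control library and Pdk4 and Acot1 lower, while Nrp1 was 48.5 CPM on average in WT controls and 84.4 to 106 CPM in the other groups.

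The second comparison asks the same of the Fpr2-deficient ventricle. The leading groups were those of WT. Of 34 fatty acid oxidation genes, 27 were called lower and 0 higher (30 adjusted over the list alone; camera adjusted p = 7.97e-24, adjusted p = 0.514 with an estimated correlation). Acot1 changed by -3.97 ± 0.46, Acot2 by -2.46 ± 0.18, Pdk4 by -2.48 ± 0.49 and Hadha, of the mitochondrial trifunctional enzyme, by -1.15 ± 0.12. Acta1 rose from 30.7 ± 6.44 to 302 ± 0.22 CPM (log2 fold change 3.30 ± 0.31, edgeR adjusted p = 0.00357) and Myh7 fell by 2.70, edgeR adjusted p = 0.0497. Postn rose from 20.8 ± 2.45 to 122 ± 25 CPM (log2 fold change 2.56 ± 0.22, edgeR adjusted p = 0.00211). Of 36 matrix genes, 14 were called higher and 1 lower (18 and 3 adjusted over the list alone; camera adjusted p = 7.31e-08, adjusted p = 0.514 with an estimated correlation), such as Sparc (1.40 ± 0.16) and Col8a1 (1.43 ± 0.18). Col1a1 was at 1.42 ± 0.36 and not called.

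Interferon genes had 18 of 25 higher and 0 lower in Fpr2-KO SuHx (23 adjusted over the list alone; camera adjusted p = 5.56e-14), antigen presentation genes 7 of 20 (9 adjusted over the list alone; camera adjusted p = 5.89e-09), cell cycle genes 10 of 30 (19 adjusted over the list alone; camera adjusted p = 6.53e-08) and macrophage markers 4 of 20 (10 adjusted over the list alone; camera adjusted p = 0.000152). With an estimated correlation each of these 4 lists had adjusted p = 0.514. Examples are Ifit3 (1.89 ± 0.23), Cxcl9 (2.05 ± 0.27), Mcm5 (1.54 ± 0.27) and Adgre1 (1.28 ± 0.24). Endothelial markers had 6 of 20 higher and 1 lower (9 and 1 adjusted over the list alone; Emcn 0.85 ± 0.14; camera adjusted p = 0.00576, adjusted p = 0.514 with an estimated correlation). Lower lists were heat shock genes, 5 of 14 (7 adjusted over the list alone; Bag3 -1.17 ± 0.13; camera adjusted p = 4.18e-06, adjusted p = 0.514 with an estimated correlation), and ribosomal protein genes, 1 of 30 (9 adjusted over the list alone; camera adjusted p = 2.38e-06, adjusted p = 0.67 with an estimated correlation). Antioxidant genes had 8 of 25 lower and 2 higher (9 and 3 adjusted over the list alone; Cat -1.32 ± 0.12; camera adjusted p = 0.0497, adjusted p = 0.67 with an estimated correlation). Immediate early genes had 1 of 19 lower (1 adjusted over the list alone; camera adjusted p = 0.0229, adjusted p = 0.514 with an estimated correlation) and genes of glucocorticoid action and fasting 3 of 15 (3 adjusted over the list alone; camera adjusted p = 0.0382, adjusted p = 0.67 with an estimated correlation). The VEGF and angiogenesis list had 2 of 18 higher and 2 lower and was not called (camera adjusted p = 0.924), with Apln at 2.58 ± 0.29 and Vegfa at -0.60 ± 0.13. Adult contractile genes had 3 of 24 higher and 2 lower (camera adjusted p = 0.855), with Mybpc3 at 0.84 ± 0.15. Glycolytic genes had 4 of 18 higher (6 and 1 lower adjusted over the list alone; Pgam2 0.78 ± 0.09) and were not called as a list (camera adjusted p = 0.0699). Anxa1 was called here (0.75 ± 0.17, edgeR adjusted p = 0.0315), as was Anxa2 (0.76 ± 0.13). Cyp1a1 went from 0.32 ± 0.17 to 211 ± 54.5 CPM (9.37 ± 0.43). Myh6 (-0.22 ± 0.19), Nppa (3.75 ± 1.83) and Nppb (0.05 ± 0.67) were not called.

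Atrial genes moved with 1 library of this comparison. Fpr2-KO SuHx library 2 held 205 CPM of Myl7 and 426 CPM of Myl4, light chains of atrial myosin, 161 CPM of Sln and 332 CPM of Bmp10, against 0, 0.963, 0 and 0.0542 CPM in library 3 of the same group. Nppa, also an atrial gene, was 741 ± 989 CPM in this group. The 8 atrial genes as a list were not called (camera adjusted p = 0.467). edgeR called 2038 genes in Fpr2-KO SuHx against control, 941 higher and 1097 lower, 689 of them at least 2-fold. The count fell to 234 without Fpr2-KO SuHx library 2, 522 without library 3, 304 and 1054 without Fpr2-KO control libraries 3 and 2, 1019 and 1017 without WT SuHx libraries 1 and 3, and 877 without WT control library 1 and Fpr2-KO SuHx library 2 together. It was 1164 with the column number as a replicate block, and DESeq2 called 3241.

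**Figure D3:**
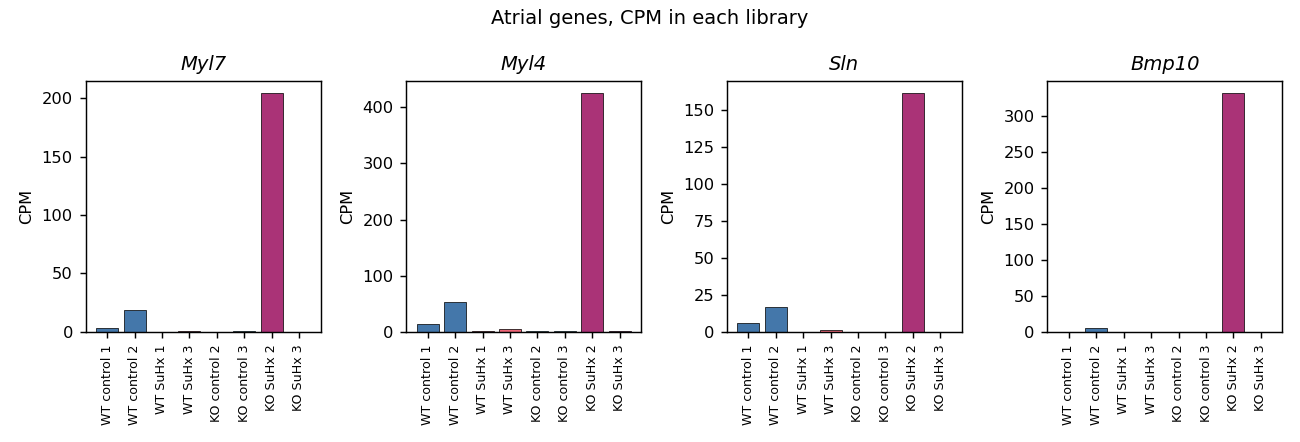
CPM (y axes, from 0) of the atrial genes Myl7, Myl4, Sln and Bmp10 in each of the 8 libraries (x axes), coloured by group. Fpr2-KO SuHx library 2 stands at 161 to 426 CPM for the 4 genes, and the next highest library, WT control 2, at 5.27 to 52.4 CPM.

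The SuHx responses of the genotypes, set side by side, share no library. The same sign was found in 71.1% of all 19083 tested genes, in 89.4% of the 4650 called in either genotype and in 99.2% of the 1307 called in both, with 636 shared among higher genes (103 by chance) and 660 among lower genes (106 by chance). Across all 19083 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.366 (Spearman 0.513), and across the 4650 genes called in either genotype at r = 0.632 (Spearman 0.772). With both genotypes averaged, the test of 4 against 4 libraries called 5646 genes, 2957 higher and 2689 lower, 1536 of them at least 2-fold. In it Acta1 was at 3.12 ± 0.22 and Postn at 2.36 ± 0.15. Interferon genes had 24 of 25 higher and 0 lower (25 adjusted over the list alone), cell cycle genes 26 of 30 higher (26 adjusted over the list alone) and fatty acid oxidation genes 30 of 34 lower (33 adjusted over the list alone). Each passed camera, and with an estimated correlation each had adjusted p = 0.348. The averaged count was 3525 without WT SuHx library 1 and 3753 without WT SuHx library 3.

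**Figure D4:**
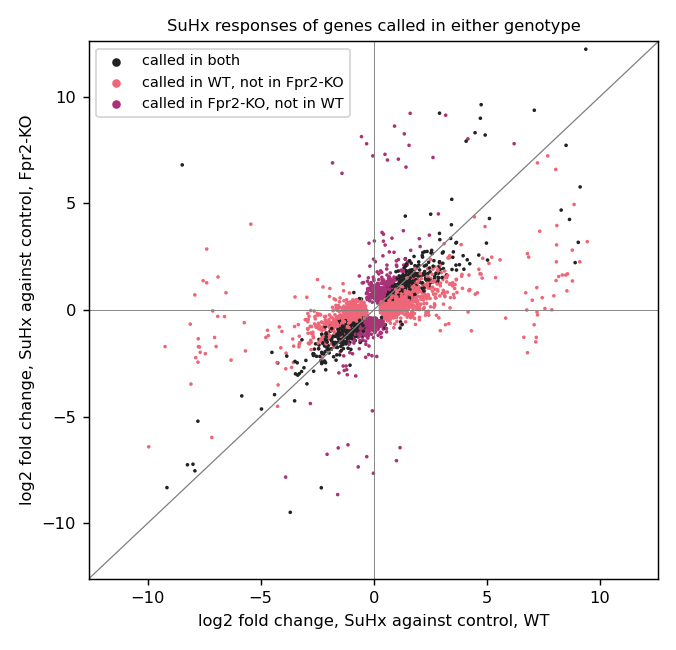
Log2 fold changes of SuHx against control in WT (x axis) and Fpr2-KO (y axis) for the 4650 genes called in either genotype, coloured by where they were called, with a line where the 2 are equal. Across these genes r was 0.632, and points beyond about 6 on either axis are mostly genes at or near 0 in a group, whose fitted values have no firm size.

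The interaction, the test of whether the SuHx response differs between genotypes, called 0 genes with edgeR. At an unadjusted p under 0.05 there were 2417 genes against 954 by chance, the smallest adjusted p was 0.0794, limma-voom called 3 genes and DESeq2 584. The genes with the smallest p, none of them called, were Cacnb2, a calcium channel subunit gene (-1.75 ± 0.17), Podxl, a sialomucin gene of vessels (-1.72 ± 0.19), and Nrp1, a VEGF co-receptor gene (-1.33 ± 0.15). Each was lower in WT controls than in the other 3 groups: Nrp1 was at 48.5 ± 1.24 CPM in WT controls, 97.6 ± 5.15 in WT SuHx, 106 ± 10.2 in Fpr2-KO controls and 84.4 ± 5.10 in Fpr2-KO SuHx. Among lists, 12 passed camera. VEGF and angiogenesis genes differed by a median of -0.59 (camera adjusted p = 6.89e-06), adult contractile genes by -0.42 (camera adjusted p = 2.37e-06) and genes of glucocorticoid action and fasting by 1.27 (camera adjusted p = 0.000128). With an estimated correlation these 3 had adjusted p = 0.343, 0.414 and 0.661. Over these lists alone 6 VEGF genes and 6 contractile genes were lower and 1 contractile gene higher, and 0 fasting genes passed. Kdr (-1.28 ± 0.20), Apln (-2.07 ± 0.40) and Pdk4 (1.76 ± 0.66) are examples, none called over all genes. The count was 718 without WT control library 2, 5 without WT control library 1, 3 without WT SuHx library 1 and 3 without WT SuHx library 3.

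The comparison of Fpr2-KO with WT in control mice asks what the genotype does at baseline. Some genes of new vessels were higher in Fpr2-KO controls, while markers of endothelial cells (1 of 20 higher, 1 lower; camera adjusted p = 0.766) and mural cells (0 of 12; camera adjusted p = 0.146) were not called as lists. The VEGF and angiogenesis list had 3 of 18 higher and 0 lower (7 adjusted over the list alone; camera adjusted p = 1.57e-05, adjusted p = 0.628 with an estimated correlation): Nrp1 (1.12 ± 0.11), Angpt2 (1.44 ± 0.21) and Apln (1.64 ± 0.30). Aplnr rose from 2.72 ± 1.30 to 13.2 ± 1.09 CPM (log2 fold change 2.27 ± 0.39, edgeR adjusted p = 0.036). Fgf16, a growth factor gene of heart muscle, was at 2.27 ± 0.34 and the T-type calcium channel gene Cacna1g at 2.02 ± 0.35. Adult contractile genes had 3 of 24 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.00488, adjusted p = 0.78 with an estimated correlation), such as Casq2 (0.73 ± 0.12) and Slc8a1 (0.56 ± 0.11) higher and Kcnip2 (-0.58 ± 0.10) lower. Hypoxia targets had 2 of 23 higher, Egln3 (1.77 ± 0.24) and P4ha2, and were not called as a list (camera adjusted p = 0.106). Macrophage markers had Ccr2 (2.56 ± 0.31) and Cx3cr1 (2.25 ± 0.47) higher of 20 (camera adjusted p = 0.0633). The immediate early genes Nr4a1 (-2.13 ± 0.33) and Btg2 (-2.24 ± 0.39) were lower (camera adjusted p = 0.103 for their list).

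Lists of fuel use and state moved with this comparison. Genes of glucocorticoid action and fasting passed camera as lower in Fpr2-KO controls (median -1.25, camera adjusted p = 2.19e-06, adjusted p = 0.654 with an estimated correlation), although 0 of 15 were called, over all genes or over the list alone. Pdk4 was at 4672 and 2544 CPM in the WT control libraries and 742 ± 25.9 CPM in Fpr2-KO controls (-2.28 ± 0.48, not called). Fatty acid oxidation genes behaved likewise, with 0 of 34 called, 7 lower adjusted over the list alone, camera adjusted p = 1.51e-05 and adjusted p = 0.78 with an estimated correlation. Smaller lists passed camera too: T and NK cell markers (adjusted p = 0.00299), antigen presentation (adjusted p = 0.00488, 2 of 20 higher), heat shock (adjusted p = 0.00793), glycolysis (adjusted p = 0.0122, 1 of 18 higher) and B cell markers (adjusted p = 0.0292) as higher, and adipocyte markers (adjusted p = 0.0148, 1 of 7 lower) as lower. With an estimated correlation camera called none of the 10. Atrial genes were also unequal, with Myl4 at 14.2 and 52.4 CPM in WT controls and 1.05 and 1.32 CPM in Fpr2-KO controls (list median -3.13, camera adjusted p = 0.439). Acta1 (0.15 ± 0.29), Postn (0.39 ± 0.21), Myh7 (-0.61 ± 0.56) and Nppb (0.33 ± 0.67) were not called.

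Nnt, the mitochondrial transhydrogenase gene, is listed as 2 nearly identical overlapping models on chromosome 13, so its values are uncertain. ENSMUSG00000116207 (119335528 to 119408952) had 696 and 242 CPM in WT controls and 0 in all 4 Fpr2-KO libraries, at least 20870-fold lower in Fpr2-KO controls with a floor of 3 counts over the group. ENSMUSG00000025453 (119335448 to 119408997) had 92.8 to 402 CPM in the 4 WT libraries and 798 to 1482 CPM in Fpr2-KO. Banp, a gene of a nuclear matrix protein, went from 4.26 ± 1.80 CPM in WT controls to 27.2 ± 5.25 in Fpr2-KO controls (log2 fold change 2.67 ± 0.28, edgeR adjusted p = 0.0166).

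edgeR called 497 genes between the control groups, 272 higher and 225 lower in Fpr2-KO, 208 of them at least 2-fold. The count was 0 without either Fpr2-KO control library, 94 without WT control library 1, 2353 without WT control library 2, 132 to 201 without any of the 4 SuHx libraries, 27 without WT control library 1 and Fpr2-KO SuHx library 2 together and 0 from the 4 control libraries alone. It was 9 with the column number as a replicate block, and DESeq2 called 1944.

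**Figure D5:**
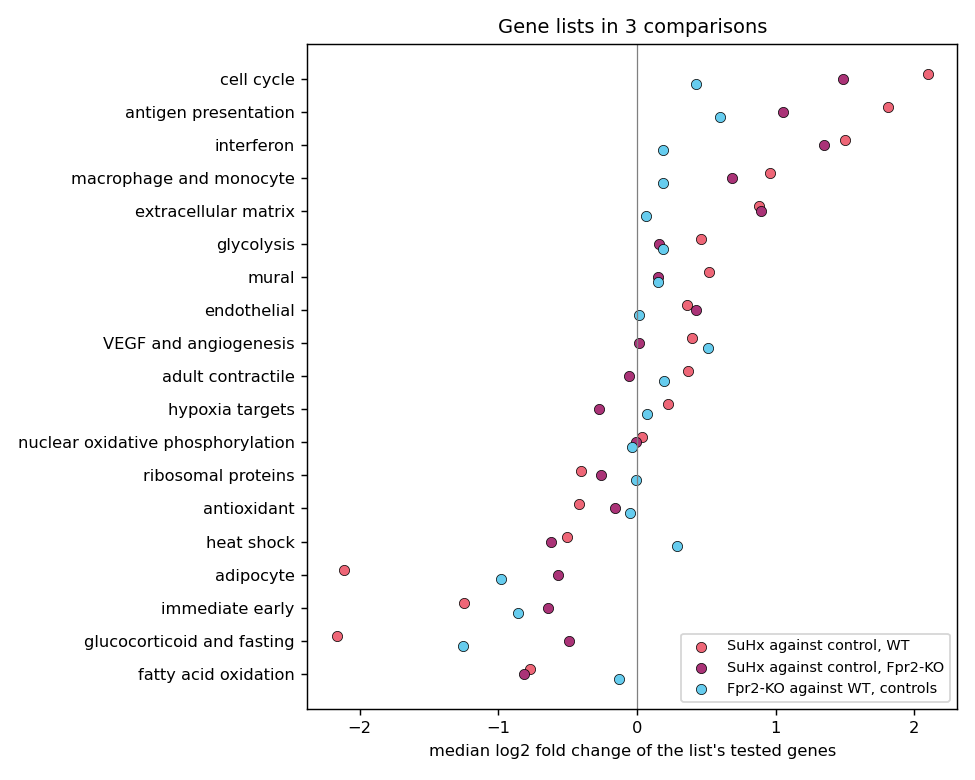
Median log2 fold change (x axis) of the tested genes of 19 lists (y axis) for SuHx against control in WT and in Fpr2-KO and for Fpr2-KO against WT in controls. Cell cycle, antigen presentation and interferon genes had medians of 1.05 to 2.1 in both SuHx responses, and genes of glucocorticoid action and fasting were lower in all 3 comparisons (-2.16, -0.49 and -1.25).

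Under SuHx, edgeR called 0 genes between Fpr2-KO and WT. At an unadjusted p under 0.05 there were 664 genes, fewer than the 954 by chance. Limma-voom called 0 and DESeq2 23. The fit shares its estimate of spread over groups whose library pairs differed. Their chi-square per degree of freedom was 24.4 in WT SuHx and 43.8 in Fpr2-KO SuHx, against 80.7 in WT controls and 57.1 in Fpr2-KO controls. A shared spread can be too strict under SuHx and too lax between controls. The counts of 497 and 0 thus do not by themselves show a larger difference in controls. The genes with the smallest p, none called, were Plac9a (1.28 ± 0.23), the proteoglycan gene Dcn (0.44 ± 0.09), at 511 ± 17.6 CPM in WT and 695 ± 39.4 in Fpr2-KO, and the second Nnt model, at least 9013-fold lower in Fpr2-KO. Postn was at 0.79 ± 0.20, Acta1 at 0.52 ± 0.28 and Kdr at -0.66 ± 0.14. Among lists, 17 passed camera with 0 genes called in any. Fatty acid oxidation genes had a median of -0.29 (1 lower adjusted over the list alone; camera adjusted p = 2.84e-17), nuclear genes of oxidative phosphorylation -0.12 (camera adjusted p = 6.31e-08) and fibroblast markers 0.35 (2 higher adjusted over the list alone; camera adjusted p = 8.22e-07). With an estimated correlation these had adjusted p = 0.499, 0.562 and 0.499, and fry called 0 lists. Adult contractile (camera adjusted p = 6.24e-07), mitochondrially coded (camera adjusted p = 3.79e-07), cell cycle (camera adjusted p = 4.39e-06), glycolysis (camera adjusted p = 0.000186), mural (camera adjusted p = 0.00162), endothelial (camera adjusted p = 0.00578), B cell (camera adjusted p = 0.0123) and VEGF (camera adjusted p = 0.0347) lists passed as lower. Ribosomal (camera adjusted p = 0.000233), T and NK cell (camera adjusted p = 0.00964), stress response (camera adjusted p = 0.0123) and hypertrophy (camera adjusted p = 0.0205) lists passed as higher, and the red cell list passed too (camera adjusted p = 0.029). None was called with an estimated correlation. Atrial genes passed as well, with a median of 5.10 that rests on Fpr2-KO SuHx library 2 (camera adjusted p = 0.0168, adjusted p = 0.65 with an estimated correlation). Nppa (3.29 ± 1.79) was not called.

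Averaged over treatments, 0 genes were called between Fpr2-KO and WT with edgeR, with 2741 at an unadjusted p under 0.05, 5 called by limma-voom and 687 by DESeq2. Fpr2 itself, with 66 counts in WT and 0 in Fpr2-KO, was among the genes not called. So was the second Nnt model, at 0 CPM in all 4 Fpr2-KO libraries. The 0 calls therefore do not show that the genotypes were alike. The count was 1151 without WT control library 2, 10 without WT control library 1 and 2 without WT SuHx library 1. Genes linked to a targeted locus can differ by descent, so the region around Fpr2 was tested. With 0 calls in the averaged comparison, calls could not be placed. At an unadjusted p under 0.05, there were 76 of the 580 tested genes within 20 Mb of Fpr2 on chromosome 17 (13.1%) against 14.4% of all other genes (Fisher's exact test, two-sided, p = 0.4). Between the control groups, 6 of the 580 genes were called (1.034%) against 2.65% elsewhere (Fisher's exact test, two-sided, p = 0.0114), and over chromosome 17 it was 12 of 936 (1.28%) against 2.67% (Fisher's exact test, two-sided, p = 0.00607), fewer in both cases. At an unadjusted p under 0.05 the shares were close: 18.97% against 20.86% within 20 Mb (Fisher's exact test, two-sided, p = 0.299). Over chromosome 17 they were 20.09% against 20.84% (Fisher's exact test, two-sided, p = 0.62). The window is part of chromosome 17, and these tests take genes as independent, which they are not.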

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

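What called attention here is a difference between the genotypes in their response to SuHx, by the interaction test on the gene lists with camera. The lists were fixed before the data were examined. The test of fasting state below was chosen only after results were seen.

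Of the lists, 12 passed the interaction test. List tests were not rerun with a library left out. How far they rest on a single library, such as Fpr2-KO SuHx library 2 with its atrial genes, was therefore not tested. The median interaction was -0.419 for adult contractile genes (camera adjusted p = 2.37e-06; median response 0.366 in WT and -0.058 in Fpr2-KO), -0.587 for VEGF and angiogenesis genes (camera adjusted p = 6.89e-06; 0.399 and 0.015), -0.277 for glycolysis (camera adjusted p = 4.68e-05) and -0.372 for mural cell markers (camera adjusted p = 0.00332). It was -0.166 for hypoxia targets (camera adjusted p = 0.0187) and -0.186 for mitochondrially coded genes (camera adjusted p = 0.00323). Among immune lists it was -0.689 for antigen presentation (camera adjusted p = 0.000591), -2.524 for B cell markers (camera adjusted p = 0.00323) and -0.31 for macrophage markers (camera adjusted p = 0.0485). It was 1.268 for glucocorticoid action and fasting (camera adjusted p = 0.000128; -2.164 in WT and -0.486 in Fpr2-KO), 0.985 for adipocyte markers (camera adjusted p = 0.00999) and 0.111 for ribosomal protein genes (camera adjusted p = 0.0304). The B cell markers were rare, with a summed level of 6.7 to 32.5 CPM per library. The adipocyte markers had a mean log2 CPM of 1.91 in Fpr2-KO SuHx library 2 and -0.17 in library 3. Of these 7 markers, 2 were at 0 in a group. Fatty acid oxidation (camera adjusted p = 0.568; -0.773 in WT and -0.816 in Fpr2-KO), endothelial markers (camera adjusted p = 0.136), nuclear genes of oxidative phosphorylation (camera adjusted p = 0.0991), interferon genes (camera adjusted p = 0.146), antioxidant genes (camera adjusted p = 0.146), immediate early genes (camera adjusted p = 0.0995) and heat shock genes (camera adjusted p = 0.0995) did not pass. None of the 12 was called with an estimated correlation (camera adjusted p = 0.343 to 0.806), fry called 0, and 0 single genes were called in the interaction.

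Between the control groups edgeR called 497 genes in the fit of all 8 libraries and 0 from the 4 control libraries alone. Under SuHx it called 0 in the fit of all 8 and 2 from the 4 SuHx libraries alone. The contrast of 497 with 0 thus depends on the spread shared over the groups. Whether all list differences lie between controls is undecided. At the preset correlation, mitochondrially coded genes, ribosomal protein genes and mural cell markers passed camera between genotypes under SuHx (adjusted p = 3.79e-07, 0.000233 and 0.00162). These lists did not pass in controls. The correlation estimated from the fit of all 8 libraries was 0.748, 0.865 and 0.0546. With it camera gave adjusted p = 0.562, 0.685 and 0.499 under SuHx. For these lists fry gave adjusted p = 0.489, 0.912 and 0.489 under SuHx, and 0 genes were called. Passing at the preset correlation alone therefore cannot place a difference under SuHx. A single outlying WT control library does not account for all of the differences between controls over the genes compared. The log2 differences of control pairs that share no library correlated at 0.44 and 0.501 over 10331 genes, against 0.138 and 0.227 for the SuHx pairs. These r describe all of those genes and do not show that the 497 calls are free of the influence of 1 library. Whether Fpr2-KO controls lie along the SuHx response is undecided, since r was 0.246 to 0.414 with the WT response but -0.029 to 0.073 with the Fpr2-KO response. No library was shared, but each response starts from a control group that also enters the difference between controls. Any control difference between genotypes thus raises r with the WT response and lowers r with the Fpr2-KO response, so these r cannot decide it. Whether the WT controls were collected in a fasted or stressed state is undecided too. The list of that state was lower in Fpr2-KO controls (median -1.254), its summed level was 7272 and 4076 CPM in WT controls against 1637 and 1800 in Fpr2-KO controls, and such a state cannot be told from an effect of the genotype here.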

How the results depend on the processing

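Of 226 results for named genes, 97 lost a call under at least 1 other setting and 92 with at least 1 library left out. The 226 include results that were never called, which could not lose a call. The other settings include a 2-fold minimum, under which each called gene below 2-fold loses its call by definition. These counts are therefore not a rate of failure. Of 2444 values under other settings, 2113 stayed the same, 283 were weaker, 42 stronger and 6 reversed, and of 1808 with a library left out, 1408 stayed the same, 368 were weaker, 18 stronger and 14 reversed. RLE shared 3889 of the WT calls, 1997 of the Fpr2-KO calls and 494 of the control calls. The planned block by title number was not run, because titles could not be joined to columns. With the number in the column name as a replicate block, added later, which leaves 2 residual degrees of freedom, the counts were 2729 in WT, 1164 in Fpr2-KO, 9 between controls, 1 under SuHx, 0 in the interaction, 4565 for SuHx averaged and 2 for genotype averaged.

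Counts moved as follows, and the cause was not tested unless fewer genes or libraries give it. DESeq2 called 3241 genes in Fpr2-KO, 1944 between controls, 23 under SuHx, 584 in the interaction and 687 for genotype averaged. Limma-voom called 3 in the interaction and 5 for genotype averaged, no filter gave 12 and 13, and the filter at 5 CPM gave 1 for genotype averaged. The 4 libraries alone gave 0 between controls and 2 under SuHx. With a 2-fold minimum the counts were 1608 in WT, 689 in Fpr2-KO, 208 between controls and 1536 for SuHx averaged. With unadjusted p and 2-fold they were 2380 in WT, 1043 between controls, 237 under SuHx, 958 in the interaction, 2080 for SuHx averaged and 405 for genotype averaged, where Fpr2 itself (fitted -7.008) passes.

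Leaving out 1 library gave ranges of 1318 to 4306 in WT, 234 to 3045 in Fpr2-KO, 0 to 2353 between controls, 0 to 3 under SuHx, 0 to 718 in the interaction, 3525 to 5890 for SuHx averaged and 0 to 1151 for genotype averaged. The fitted value of Fpr2 (-7.061 to -6.969) is set by the prior count, as all 4 Fpr2-KO libraries held 0 counts, and is not a measured size. The agreement of both responses was r = 0.2926 to 0.3845. Without WT control library 1 and Fpr2-KO SuHx library 2 together, a choice added later, the counts were 2214, 877, 27, 2 and 3 (WT, Fpr2-KO, controls, SuHx, genotype averaged). Agreement was 0.4974 at 5 CPM and 0.6317 among called genes.

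Camera with an estimated correlation called 0 lists and 0 terms in all 7 comparisons, and fry called 17 lists in WT, 15 for SuHx averaged, 1 in Fpr2-KO and 0 between controls, under SuHx, in the interaction and for genotype averaged. The cause was not tested.

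Genes that reversed, none of them called, are given with their range over left-out libraries. In Fpr2-KO SuHx, Nppb was 0 with limma-voom, -0.148 with the replicate block, -0.391 without Fpr2-KO control 2, -0.782 without Fpr2-KO SuHx 2 and -0.774 without the pair (-0.782 to 0.685). Nppa was -0.405 and -0.397 in the last 2 settings (-0.405 to 4.931) and Myh6 0.173 without Fpr2-KO control 2 (-0.53 to 0.173). Between controls, Myh7 was 0.067 without WT control 1 and without the pair (-1.515 to 0.067), and without Fpr2-KO control 3 Acta1 was -0.081 (to 0.352) and Nppb -0.306 (to 0.768). In WT, Anxa1 was -0.054 without WT control 2 (to 0.233) and Nppb 0.001 without WT SuHx 3 (from -1.289). Under SuHx, Nppa was -0.858 without Fpr2-KO SuHx 2 (to 4.248) and -0.86 without the pair. For genotype averaged, Wdfy1 was -0.105 without Fpr2-KO SuHx 3 (to 0.32), and Entpd4 was -0.074, -0.02 and -0.033 without WT control 2, WT SuHx 1 and Fpr2-KO control 2 (to 0.144). The cause was not tested.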

Other observations

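Chosen only after results were seen were the count of 2-fold atrial genes, the test on summed Nnt counts and the comparison of Nnt and background genes within each treatment. The annotated terms below were tested over the 1361 GO terms, and none was called with an estimated correlation.

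Terms of collagen and of translational initiation passed in both genotypes. Collagen trimer genes had 26 of 57 higher and 0 lower in WT (camera adjusted p = 1.69e-05) and 17 higher and 2 lower in Fpr2-KO (camera adjusted p = 3.71e-06). Genes of cytoplasmic translational initiation had 11 of 17 lower in WT (camera adjusted p = 1.26e-06) and 7 in Fpr2-KO (camera adjusted p = 1.46e-05). Acetylglucosaminyltransferases, which build glycans, had 15 of 24 higher and 0 lower with both genotypes averaged (camera adjusted p = 0.000102). Regulators of alternative mRNA splicing had 13 of 55 lower and 0 higher in Fpr2-KO (camera adjusted p = 3.71e-06). Autophagosome genes had 5 of 46 lower in Fpr2-KO controls (camera adjusted p = 0.000165).

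Fpr2-KO SuHx library 2 held atrial genes at levels that its partner lacked. In a second list of 14 atrial genes, written before their values were read, the median log2 ratio of the libraries was 0.534, against -0.421, -0.155 and -0.184 in the other groups, between the limits set for and against atrial tissue in that sample. Of these genes, 4 exceeded 2-fold in library 2 over library 3, with Mybphl at 58.8 against 0.231 CPM. In the other groups 0 did in the lower-numbered library over the higher-numbered one. Some did the other way there: Mybphl was 4.324 CPM in WT control library 2 against 1.725 in WT control library 1. Kcna5 was 29.09 CPM in WT SuHx library 3 against 11.75 in WT SuHx library 1. In Fpr2-KO SuHx library 3, 1 of 8 genes of the first list exceeded 2-fold over WT SuHx, a count that restates the pattern. It replaced a first count of 4 of 8 above both WT SuHx libraries (2.667 by chance). Whether both Fpr2-KO SuHx samples share a response was therefore not tested independently.

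For Nnt, a split of reads between the overlapping models is not enough, as the lowest summed level in Fpr2-KO was 1.011 times the highest in WT over all libraries, and 1.83 times in controls and 1.46 times under SuHx, ratios within treatment that were added later. A difference of C57BL/6J and C57BL/6N background was looked for in Wdfy1, Entpd4 and Ide. Of these, 0 separated the genotypes over all libraries (median size 0.137), but Ide was lower in every Fpr2-KO library within each treatment (-0.22 ± 0.08, edgeR adjusted p = 0.276), so such a difference is left open. No test set an effect of Fpr2 loss on Nnt apart from these.

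Cyp1a1 is a target of the aryl hydrocarbon receptor, and the Sugen compound is a known ligand of it, so other targets were tested. Of 7, 3 were called higher with both genotypes averaged: Ahrr (1.96 ± 0.16, edgeR adjusted p = 0.000202), Cyp1b1 (1.72 ± 0.29, edgeR adjusted p = 0.00636) and Ugt1a7c (1.22 ± 0.20, edgeR adjusted p = 0.00312). Nqo1 was lower (-0.40 ± 0.10, edgeR adjusted p = 0.0182), and 3 were not called. The 3 met the number set beforehand for activation of the receptor, which the compound or another cause could bring. That number made no allowance for the share of all genes called higher in this comparison, 2957 of 19083. Cyp1b1 was also a member of the estrogen, apelin and BMP list of the main tests.

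Of the 35 splits of the libraries into 4 and 4, 1 gave as many calls as SuHx against control, which was that split itself with 4549, and the highest other gave 1. The split by genotype gave 0, which all 35 reach, and the highest other, the split by treatment, gave 4549. The model of a split held no treatment term. The SuHx effect therefore stayed, in whole or in part, in the spread within the groups of every split but that by treatment. For that reason the splits could not test the genotype.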
